A study of Mus musculus with 15 samples.

How the data were processed

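Gene expression was measured by RNA sequencing in 15 libraries of sorted mature thymocytes from mixed bone marrow chimeras on a C57BL/6 background, 3 libraries in each of 5 groups. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Plus Micro kit, libraries were made with Takara SMARTer Ultra Low Input reagents, and pools were read as 101 bp pairs on a NovaSeq. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic, STAR, HTSeq, DESeq2 and the build mm39. They do not give the roles of these tools, and the gene annotation, the strand setting and the other versions are not given in the sources used here. Gene symbols were used exactly as deposited, and no coordinates were used.

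The authors deposited raw read counts per gene, 1 set per library, together with a table of the counts of all libraries. The counts of each library were identical between both kinds of deposited file. The authors also deposited normalised values named FPM, which are CPM, the counts scaled by each library's gene total alone: scaled back by the library's gene total, the values were whole numbers in 100% of cases (tolerance 0.01). Each table of the whole series held 3 further columns of per-library values that match no sample label and were not used here. Each library had 5 summary lines that name no gene, and they held 16.7%, 16.9%, 18.5%, 18.8% and 17.6% of all counted reads on average in WT CD4 SP, WT CD8 SP, Thpok-RKF- CD8 SP, Thpok-RKF- CD4+CD8+ and Thpok-RKF+ CD4+CD8+ libraries. They were left out of library sizes and tests. Gene totals lay between 37311823 and 48607260 counts. No pair of replicates agreed within sampling noise: the chi-square of their counts over its degrees of freedom, over genes with at least 10 counts, ran from 11.1 to 190.4.

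Samples were grouped by the population and genotype in the labels. Changes were tested with the edgeR quasi-likelihood F test on the deposited counts, with TMM normalisation, all 15 libraries in 1 model of group means, and the edgeR expression filter (minimum count 10, minimum total 15), which kept 16550 of 53762 genes. Adjusted p-values are by the Benjamini-Hochberg method with a threshold of 0.05, and standard errors are the log2 fold change divided by the square root of F. Levels are CPM with TMM-scaled library sizes, as mean ± SD. The comparisons were WT CD4 SP with WT CD8 SP, Thpok-RKF+ with Thpok-RKF- CD4+CD8+, Thpok-RKF- CD4+CD8+ with Thpok-RKF- CD8 SP, Thpok-RKF- CD8 SP with each WT group, each CD4+CD8+ group with WT CD4 SP, and a difference of differences. A fold against a group with no counts was computed against a floor of 3 counts over the group. With 1 to 3 counts the ratio was given with an exact binomial interval at 95%. These intervals and floors cover counting error only.

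Lists of genes, 19 in all, covered helper and cytotoxic lineage genes, thymocyte transcription factors, T helper effectors, regulatory, NKT and gamma-delta T cells, immature thymocytes, maturation and egress, TCR response, effector and memory genes, interferon response, NuRD components, cell cycle, dissociation stress, B cells, myeloid cells, stroma and erythroid cells. Of the listed genes, 5 symbols matched no gene in the tables used here, 4 of gamma-delta T cells and 1 of stroma. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 19 lists, and again with a correlation estimated from the data. Counts of members are also given adjusted over the list alone. The fry test asks whether a list's genes move, on balance, 1 way, and its mixed form whether they change in either direction, and neither sets the list against other genes. Genes changed at least 2-fold between WT groups formed sets called helper and cytotoxic after the WT cells they were higher in, whatever their function. Camera tested these in mutant libraries, which were in the same fit. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. Always named were Zbtb7b, Runx3, Cd4, Cd8a, Cd8b1 and Gata3, with up to 4 members of a list by smallest adjusted p. Also named were the 10 largest rises and falls for WT CD4 SP against WT CD8 SP and for Thpok-RKF+ against Thpok-RKF-, and 5 of each elsewhere. These had to pass the test, have a mean log2 CPM of at least 3 and not overlap between groups; receptor segments, predicted models, Xist and Y-linked genes were left out. Jun, Hspa1a, Gbp2, Rabl2, Cpne8, Dcst2 and Gm15417 fell outside the rule and were named after their values were seen.

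Alternatives were relative log expression size factors, no low-count filter, the DESeq2 Wald test, only the compared groups in the fit, the replicate number in the model, limma-trend on log2 of the deposited values plus 1, a required 2-fold change, sets without a fold threshold, an estimated correlation, and each library left out in turn. Leaving out the libraries numbered 1, a term for them, a covariate for the share of reads outside genes, lists without Zbtb7b, lists without the sorted genes Cd4, Cd8a and Cd8b1 and sets without cell cycle genes were added after seeing the data. The pipeline was tested on simulated data made from the real means and library sizes, where 3 of 16350 unchanged genes were called in the comparison of Thpok-RKF+ with Thpok-RKF- CD4+CD8+ cells. Gene order came from the RefSeq annotation of the assembly GRCm38.p6, another build than the one the submitters name, so it served only to say which genes neighbour each other, and 14636 of 16550 tested symbols matched. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.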

Results

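RNA was sequenced from 15 libraries of mature mouse thymocytes in 5 groups of 3. The cells were sorted from thymuses of irradiated hosts given a mixture of wild-type and mutant bone marrow. Every sort gate was low for CD44, CD24 and CD69 and high for the T cell receptor beta chain. Wild-type (WT) CD4 single-positive (SP) cells came from hosts lacking B2m, a chain needed for MHC class I. WT CD8 SP cells came from hosts lacking I-Ab, an MHC class II chain. The 3 mutant groups came from B2m-deficient hosts. Their marrow donors carried floxed Thpok alleles, a floxed Runx3 allele opposite a Runx3 dYFP allele, and Cd4-Cre, which deletes floxed sequence in developing T cells. Donors either lacked or carried Thpok-RKF, a name that the labels do not explain. Thpok-RKF- donors gave a CD8 SP and a CD4+CD8+ group, and Thpok-RKF+ donors gave a CD4+CD8+ group. Gene totals ran from 37311823 to 48607260 counts per library, and 16550 of 53762 genes were tested. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

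Zbtb7b, which encodes the helper-lineage transcription factor Thpok, was read first as the targeted gene. It was counted at 64, 79.2 and 27.4 CPM, counts scaled to a common library size, in the WT CD4 SP libraries and at 0.239, 0.376 and 0.0933 CPM in the WT CD8 SP libraries. Thpok-RKF- CD8 SP libraries had 2.11, 2.51 and 1.92 CPM, Thpok-RKF- CD4+CD8+ libraries 2.77, 2.95 and 1.67, and Thpok-RKF+ CD4+CD8+ libraries 812, 769 and 823. Zbtb7b in the 6 Thpok-RKF- libraries lay below every WT CD4 SP library. The labels do not say whether reads from Thpok-RKF were counted as Zbtb7b. Runx3, a transcription factor of the cytotoxic lineage, stood at 28.8 ± 4.96 CPM (SD, n = 3) in WT CD4 SP and 206 ± 13.2 in WT CD8 SP cells. It stood at 267 ± 34.4, 279 ± 14.7 and 305 ± 49.1 in Thpok-RKF- CD8 SP, Thpok-RKF- CD4+CD8+ and Thpok-RKF+ CD4+CD8+ cells. Zbtb7b and Runx3 counts each cover the whole gene, so they do not check whether the floxed parts were deleted.

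**Figure D1:**
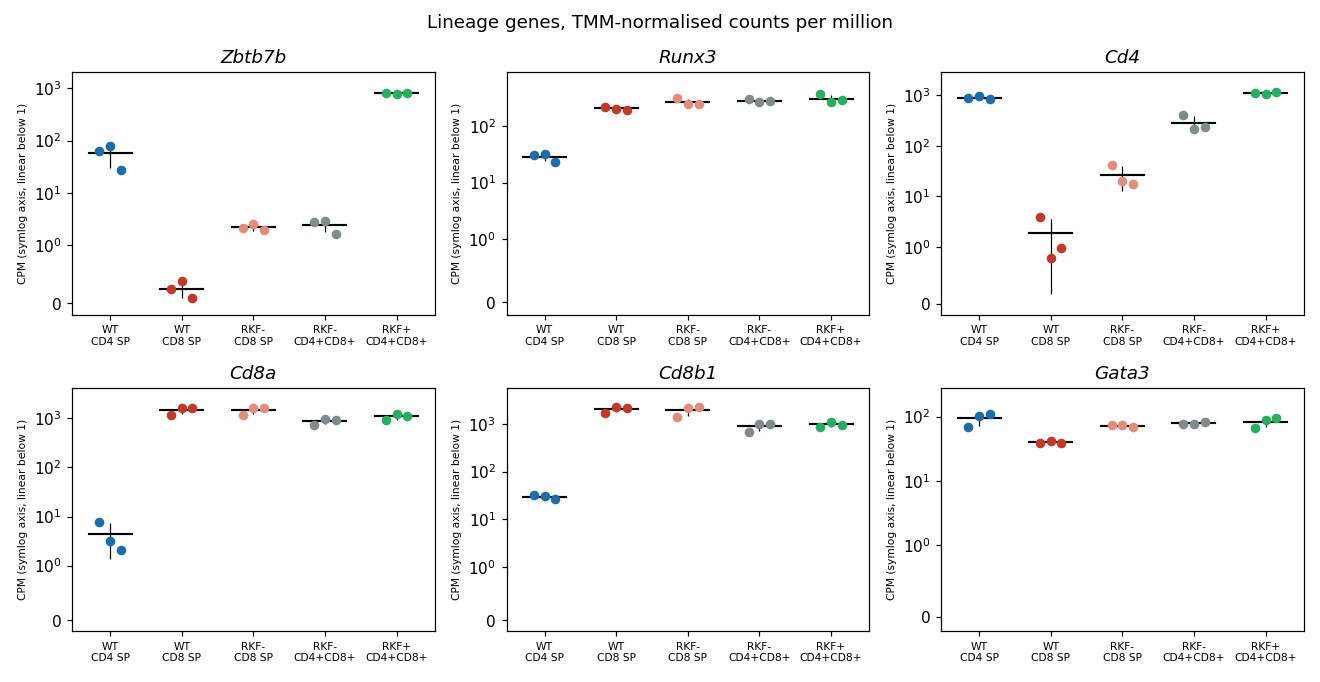
Each panel shows 1 gene, with CPM on a symlog axis that is linear below 1 against the 5 groups (RKF stands for Thpok-RKF); points are the 3 libraries of a group, horizontal lines the mean and vertical lines the SD. Zbtb7b lay at 801 ± 28.9 CPM in Thpok-RKF+ cells against 56.8 ± 26.6 in WT CD4 SP cells.

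Libraries numbered 1 stood apart from the others of their groups. Jun, an immediate early gene, was 3.12 log2 units higher in them with group in the model (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00318), and its level was highest in the library numbered 1 in 5 of 5 groups. The same test called 1543 genes for number 1 against the rest, 0 for number 2 and 0 for number 3, where 449 and 1016 genes had an unadjusted p below 0.05. The share of reads outside genes was highest in the library numbered 1 in 5 of 5 groups, and was 11.2% in Thpok-RKF+ replicate 1 against 5.28% and 5.65% in replicates 2 and 3. The macrophage lysozyme gene Lyz2 was highest in the library numbered 1 in 2 of 5 groups and did not pass the same test (adjusted p = 0.297). It stood at 24.5, 0.194 and 0.876 CPM in Thpok-RKF+ replicates 1, 2 and 3 and at 28.4, 0.393 and 0 CPM in WT CD4 SP replicates 1, 2 and 3, and at most at 4.43 CPM in every library of the other groups. Cell cycle and interferon lists were lower and immature thymocyte markers and stress genes higher in libraries numbered 1 by camera (adjusted p = 0.000149, 0.000149, 0.00624 and 0.0188, but 0.692, 0.692, 0.187 and 0.692 with an estimated correlation). Counts of changed genes are therefore given also with these 5 libraries left out and with a term for them, both chosen after seeing the data.

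WT CD4 SP and WT CD8 SP cells gave the helper and cytotoxic reference, although host differed with lineage, so host and lineage could not be separated. Cd4 was 889 ± 74.6 CPM in CD4 SP cells and 1.88 ± 1.71 in CD8 SP cells, a log2 fold change of 8.90 ± 0.58 (SE, n = 3 per group). Other large rises in CD4 SP cells were found for St8sia6 (8.46 ± 0.53), Zbtb7b (7.91 ± 0.47), Tnfrsf4 (6.40 ± 0.41), which encodes the OX40 costimulatory receptor, Ptgir (5.93), a prostacyclin receptor gene, Adh1 (5.72), Khdrbs3 (5.18), Cd40lg (5.14), the CD40 ligand of helper cells, Ly6c1 (4.82) and Il2ra (4.70), a chain of the interleukin 2 receptor. CD8 SP cells had higher levels of Haao (log2 fold change -10.45 ± 0.48), Slc6a19 (-8.85 ± 0.48), the cytotoxic granule gene Nkg7 (-8.71 ± 0.45), Cd8a (-8.42 ± 0.43), Adgrg5 (-7.31), Itgae (-6.68), which encodes CD103, Klrd1 (-6.43), Cd8b1 (-6.09), Cacng4 (-5.88) and Baiap3 (-5.87). Runx3 fell by 2.84 ± 0.15 on the log2 scale and Gata3, a helper-lineage factor, rose by 1.24 ± 0.16 in CD4 SP cells (edgeR, adjusted p = 2.18e-08 and 0.000111). The WT groups were sorted apart by CD4 and CD8, so Cd4, Cd8a and Cd8b1 are no finding between them. Ly6c1 shares sequence with Ly6c2, so the division of reads between these genes is uncertain. Libraries of the groups did not overlap for 36.3% of all genes, where chance gives 10%. Folds moved by over 1.5 times in Cd8a (log2 -9.08) without WT CD4 SP replicate 1, Slc6a19 (-12.29) without WT CD4 SP replicate 2, Baiap3 (-6.64), Klrd1 (-7.87) and Nkg7 (-9.47) without WT CD4 SP replicate 3, Cd4 (9.99) without WT CD8 SP replicate 1 and Adh1 (6.66) and Khdrbs3 (6.40) without WT CD8 SP replicate 2.

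Of 12 helper lineage genes, 7 rose and 1 fell in WT CD4 SP cells (7 rose and 1 fell adjusted over the list alone), and of 25 measured cytotoxic lineage genes 19 fell and 2 rose (2 rose and 19 fell adjusted over the list alone). Both lists passed camera, which sets a list against the other genes (adjusted p = 1.32e-16 and 2.5e-46; 8.62e-05 and 3.36e-06 with an estimated correlation). Regulatory T cell markers 10 rose and 1 fell of 14 (10 rose and 1 fell adjusted over the list alone; adjusted p = 4.18e-13, and adjusted p = 0.0174 with an estimated correlation), among them Foxp3, their defining transcription factor (4.43 ± 0.37). All 18 cell cycle genes fell (18 fell adjusted over the list alone), including the replication helicase subunit genes Mcm6 (-1.65), Mcm3 (-1.82) and Mcm5 (-2.10) and the topoisomerase gene Top2a (-2.31), with adjusted p = 9.1e-22, and adjusted p = 0.024 with an estimated correlation. Of interferon response genes 17 rose and 2 fell of 26 (18 rose and 3 fell adjusted over the list alone), with Irf9 at 1.11 ± 0.12 and Usp18 at 1.64 ± 0.21. The list gave adjusted p = 1.61e-09, but adjusted p = 0.0846 with an estimated correlation. Of effector and memory genes 3 rose and 10 fell of 21 (3 rose and 10 fell adjusted over the list alone), including Lgals1 (-1.71) and Anxa2 (-1.75) among the falls. Of maturation and egress genes 6 rose and 3 fell of 15 (8 rose and 3 fell adjusted over the list alone), including Slfn1 (1.74). Their adjusted p = 0.000448 and 0.00102, and adjusted p = 0.0837 and 0.0845 with an estimated correlation. Of components of the chromatin-remodelling NuRD complex 1 rose and 3 fell of 14 (1 rose and 8 fell adjusted over the list alone), with Gatad2a at -0.90 ± 0.09 and Chd3 at 1.03 ± 0.20. Of NKT and innate-like markers 2 rose and 5 fell of 13 (3 rose and 5 fell adjusted over the list alone), with Cd160 at -5.40 ± 0.37. These lists had adjusted p = 0.0179 and 0.0418, and adjusted p = 0.0845 and 0.126 with an estimated correlation. Lists of thymocyte transcription factors (8 rose and 6 fell of 24, Satb1 by 0.71 ± 0.08 and Ets1 by 0.68 ± 0.09 among the rises), T cell receptor (TCR) response genes (4 rose and 3 fell of 18) and T helper effector genes (3 rose and 2 fell of 14) did not pass camera (adjusted p = 0.319, 0.104 and 0.19). Adjusted over each of these lists alone, 9 rose and 8 fell, 4 rose and 3 fell, and 4 rose and 2 fell. Without the libraries numbered 1, 9 of 19 lists passed, 9 of them among the 10 that passed with them.

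Markers of other cells that a thymocyte gate could hold moved in part between the WT groups. Of 7 measured B cell markers, Cd79b (-5.05) and Ighd (-7.68) fell in CD4 SP cells (1 rose and 2 fell adjusted over the list alone; adjusted p = 0.0418 for the list, and adjusted p = 0.0846 with an estimated correlation). That list had adjusted p = 0.132 without the libraries numbered 1 and 0.06 with a term for them. The myeloid, stromal, erythroid, gamma-delta T cell, immature double-positive and dissociation stress lists did not pass (adjusted p = 0.175, 0.753, 0.148, 0.414, 0.753 and 0.242). In that order they had median log2 fold changes of 2.33, -0.90, 3.11, 0.33, 0.23 and 0.30, which stayed with members without a count in 1 group set at their bound, means at those bounds of 1.57, -1.37, 3.78, 0.43, 0.20 and 0.21, and camera directions of up, up, up, up, down and up. Over all genes tested 3, 2, 2, 0, 1 and 3 members rose and 1, 1, 0, 0, 2 and 2 fell, and adjusted over the list alone 6, 2, 2, 2, 1 and 3 rose and 1, 1, 0, 0, 2 and 2 fell. Members with calls in edgeR included Themis (-0.73) and Mns1 (-1.62), which fell, and Cd1d1 (1.35) and Epcam (1.14), which rose. The collagen gene Col1a1 had no count in CD4 SP cells and was at least 45.9-fold lower there.

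In total 2981 genes differed between the WT groups, 1277 higher and 1704 lower in CD4 SP cells. The count was 1908 without WT CD8 SP replicate 2, 3003 without the libraries numbered 1 and 3791 with a term for them. A requirement of at least 2-fold change left 1397.

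The central comparison set Thpok-RKF+ against Thpok-RKF- CD4+CD8+ cells, which differed by label only in Thpok-RKF. Zbtb7b rose by 8.34 ± 0.42 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 5.22e-08). Cd247, the zeta chain of the TCR complex, rose by 2.58 ± 0.10, from 436 ± 20.3 to 2616 ± 211 CPM. Ckb, which encodes a creatine kinase, fell by 8.64 ± 0.49 on the log2 scale, from 56.7 ± 5.35 to 0.135 ± 0.213 CPM. Its Thpok-RKF+ counts were 18, 0 and 1 in replicates 1, 2 and 3, so replicate 1 set its level, and by limma on log2 of CPM plus 1 its value was -5.71. Syt10, a synaptotagmin gene, had 2 counts over the Thpok-RKF- libraries and 5731 over the Thpok-RKF+ libraries, a ratio of 2940 with a 95% counting interval of 813 to 24300. Other rises were found for Cd4 (1.97 ± 0.42), Cd160 (1.90 ± 0.31), Dhrs7 (1.78 ± 0.22), Dapl1 (1.77 ± 0.27), Sardh (1.64 ± 0.27), H2-Q6 (1.57 ± 0.23) and Ly6c2 (1.54 ± 0.22). Other falls were found for Pcsk1 (-2.12 ± 0.40), Foxp3 (-1.87 ± 0.33), Myo10 (-1.80 ± 0.39), Cacng4 (-1.77 ± 0.32), Slc28a2b (-1.62 ± 0.19), Slc6a19 (-1.61 ± 0.30), Amigo2 (-1.60 ± 0.12), Cep170b (-1.59 ± 0.32) and Actn2 (-1.52 ± 0.23). Runx3, Cd8a, Cd8b1 and Gata3 had log2 fold changes of 0.13 ± 0.14, 0.32 ± 0.31, 0.14 ± 0.18 and 0.08 ± 0.16 and did not pass. H2-Q6, Ly6c2 and Slc28a2b have close paralogs, so their reads are uncertain. Calls were lost for 9 of these genes with 1 library left out. Cd4, Cd160, Foxp3 and Myo10 had adjusted p = 0.0536, 0.0516, 0.0513 and 0.125 without Thpok-RKF- CD4+CD8+ replicate 1. Cd4, Cd160, Sardh, Pcsk1, Myo10, Cacng4, Slc6a19 and Cep170b had adjusted p = 0.18, 0.0618, 0.0666, 0.0833, 0.0828, 0.0738, 0.076 and 0.126 without Thpok-RKF- CD4+CD8+ replicate 2. Cd4, Sardh, Pcsk1, Myo10, Cacng4, Slc6a19 and Cep170b had adjusted p = 0.178, 0.0573, 0.0626, 0.134, 0.0706, 0.0799 and 0.1 without Thpok-RKF- CD4+CD8+ replicate 3. Cd4, Sardh, Pcsk1, Foxp3, Myo10, Cacng4, Slc6a19 and Cep170b had adjusted p = 0.0949, 0.0502, 0.108, 0.0693, 0.137, 0.0928, 0.0846 and 0.137 without Thpok-RKF+ CD4+CD8+ replicate 2. Cd4, Sardh, Foxp3, Myo10, Cacng4, Slc6a19 and Cep170b had adjusted p = 0.131, 0.0569, 0.0764, 0.147, 0.0905, 0.123 and 0.16 without Thpok-RKF+ CD4+CD8+ replicate 3. With these groups alone in the fit, adjusted p = 0.0638 for H2-Q6, 0.0638 for Foxp3, 0.153 for Myo10, 0.128 for Cep170b and 0.0722 for Actn2. The fold moved by over 1.5 times in Ckb (log2 -11.96) without Thpok-RKF+ CD4+CD8+ replicate 1 and Ckb (-8.05) without Thpok-RKF+ CD4+CD8+ replicate 2.

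**Figure D2:**
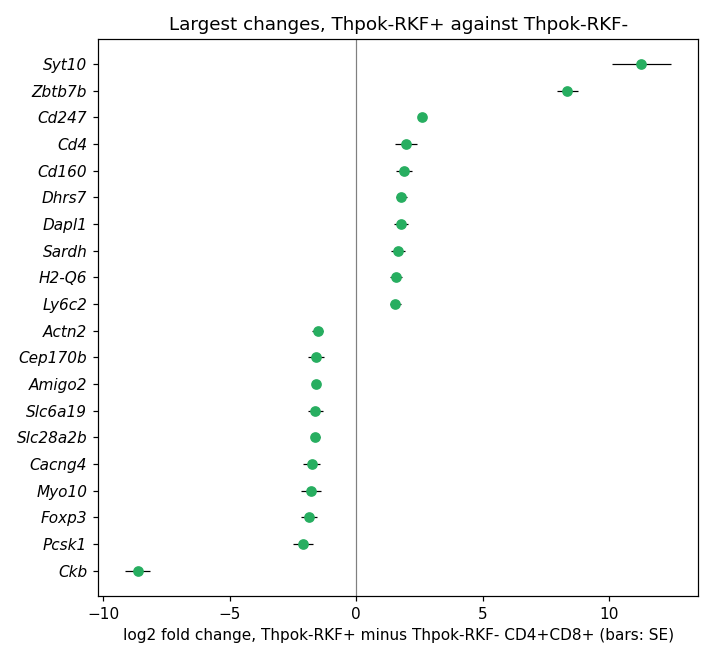
Points are log2 fold changes, Thpok-RKF+ minus Thpok-RKF- CD4+CD8+ cells (n = 3 libraries each), and bars are SE, for the 10 largest rises and 10 largest falls chosen by the stated rule. Zbtb7b lay at 8.34 and Ckb at -8.64; the fitted value of Syt10 depends on the prior count, because 2 counts were seen in Thpok-RKF- libraries.

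Among the lists, 2 of 12 helper genes rose in Thpok-RKF+ cells, Zbtb7b and Cd4 (3 rose adjusted over the list alone), with adjusted p = 0.000262, and adjusted p = 0.0247 with an estimated correlation. The list call rested on Zbtb7b: with that gene taken out of every list, a test chosen after seeing the data, the other 11 helper genes had adjusted p = 0.513 (0.647 with an estimated correlation) and a median log2 fold change of 0.08. Taking it out left 3 of 19 lists past the threshold and 0 with an estimated correlation, and the NKT list then had adjusted p = 0.0511. Of 25 cytotoxic genes, Ly6c2, Dapl1 and Cst7 (0.72 ± 0.15), a cystatin gene, rose (8 rose and 2 fell adjusted over the list alone; adjusted p = 0.00244, and adjusted p = 0.0942 with an estimated correlation). Of 18 cell cycle genes, Top2a (-1.37 ± 0.26) and the proliferation marker Mki67 (-1.45 ± 0.32) fell (9 fell adjusted over the list alone; adjusted p = 7.61e-06, and adjusted p = 0.34 with an estimated correlation). Among 14 regulatory T cell markers Gpr83 (-1.31 ± 0.15) and Foxp3 fell and Tnfrsf18 (0.92 ± 0.20) rose (2 rose and 3 fell adjusted over the list alone; adjusted p = 0.0337, and adjusted p = 0.555 with an estimated correlation). Cd160 was the single NKT and innate-like marker called of 13 (1 rose adjusted over the list alone; adjusted p = 0.0408, and adjusted p = 0.267 with an estimated correlation). Nr4a1, an early TCR response gene, rose by 1.33 ± 0.29, and its list of 18 did not pass (1 rose adjusted over the list alone; adjusted p = 0.47). The NuRD list did not pass either (adjusted p = 0.909), and 0 of its 14 members were called by edgeR or adjusted over the list alone, 0 by limma and 1 by DESeq2, with 2 at an unadjusted p below 0.05. Without Thpok-RKF+ replicate 1, 1677 genes passed. These included NuRD's Chd3 (-0.66), Mta1 (-0.78), Cdk2ap1 (0.61) and Rbbp7 (0.51) (adjusted p = 0.00977, 0.0242, 0.0333 and 0.0436). Chd3, Cdk2ap1 and Rbbp7 passed without the libraries numbered 1 (adjusted p = 0.0267, 0.0285 and 0.0179). Cdk2ap1 passed by DESeq2 and with a term for them (adjusted p = 0.0345 and 0.0334). Cd4, Cd160, Foxp3, Cst7, Top2a, Mki67 and Ighd had adjusted p = 0.0536, 0.0516, 0.0513, 0.113, 0.0538, 0.0998 and 0.135 without Thpok-RKF- CD4+CD8+ replicate 1. Cd4, Cd160, Cst7, Tnfrsf18, Nr4a1, Top2a, Mki67 and Ighd had adjusted p = 0.18, 0.0618, 0.0758, 0.175, 0.19, 0.076, 0.143 and 0.124 without Thpok-RKF- CD4+CD8+ replicate 2. Cd4, Cst7, Tnfrsf18, Nr4a1, Top2a and Mki67 had adjusted p = 0.178, 0.159, 0.172, 0.184, 0.0644 and 0.128 without Thpok-RKF- CD4+CD8+ replicate 3. Cd4, Foxp3, Cst7, Tnfrsf18, Nr4a1, Top2a, Mki67 and Ighd had adjusted p = 0.0949, 0.0693, 0.137, 0.192, 0.192, 0.111, 0.162 and 0.137 without Thpok-RKF+ CD4+CD8+ replicate 2. Cd4, Foxp3, Cst7, Tnfrsf18, Nr4a1, Top2a, Mki67 and Ighd had adjusted p = 0.131, 0.0764, 0.129, 0.149, 0.188, 0.0764, 0.232 and 0.0794 without Thpok-RKF+ CD4+CD8+ replicate 3. By limma on normalised values adjusted p = 0.0609 for Cst7, with these groups alone in the fit adjusted p = 0.203 for Cst7, 0.157 for Tnfrsf18, 0.169 for Nr4a1 and 0.191 for Ighd, and with a covariate for reads outside genes adjusted p = 0.065 for Tnfrsf18, 0.0895 for Nr4a1 and 0.0539 for Mki67. Without the libraries numbered 1, 6 of 19 lists passed, 3 of them among the 5 that passed with them. The regulatory T cell and NKT lists then had adjusted p = 0.594 and 0.155, and the TCR response, interferon and stress lists passed (adjusted p = 0.0431, 0.0317 and 0.0317). Among markers of other cells, the immunoglobulin gene Ighd rose by 3.40 ± 0.73, from 0.326, 0.0443 and 1.02 to 4.8, 6.67 and 3.25 CPM, the single B cell marker called of 7 (1 rose adjusted over the list alone), and had adjusted p = 0.0623 without the libraries numbered 1. Myeloid, stromal, erythroid and gamma-delta markers had 0 calls by edgeR, 1, 0, 0 and 0 by DESeq2 and 2, 1, 2 and 1 at an unadjusted p below 0.05. The macrophage complement genes C1qa and C1qb had no count in Thpok-RKF- and 227 and 512 counts in Thpok-RKF+ libraries, at 4.8, 0 and 0 and 10.6, 0.238 and 0 CPM in replicates 1, 2 and 3, and did not pass (adjusted p = 0.28 and 0.287). B cell, myeloid, stromal, erythroid and gamma-delta lists had adjusted p = 0.47, 0.862, 0.178, 0.483 and 0.47. The fold moved by over 1.5 times in Ighd (log2 4.70) without Thpok-RKF- CD4+CD8+ replicate 3.

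In total 159 genes passed, 97 higher and 62 lower in Thpok-RKF+ cells, and 16.4% of all genes had libraries that did not overlap, where chance gives 10%. The balance of rises and falls was not settled, with 203 higher and 225 lower with no low-count filter and 118 higher and 114 lower with a covariate for reads outside genes. The count was 1677 without Thpok-RKF+ replicate 1, with 159 of the 159 kept, and 63 and 53 without its replicates 2 and 3. It was 92, 50 and 50 without Thpok-RKF- replicates 1, 2 and 3. Leaving out all libraries numbered 1 gave 1753, a term for them 350, DESeq2 708, no low-count filter 428, limma on normalised values 287, a fit of these groups alone 52 and a required 2-fold change 99. In a simulation of this comparison over 16550 genes, 11.9% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 81.8% of those changed 4-fold were recovered, so most 1.5-fold changes were not detectable.

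Genes that separated the WT groups by at least 2-fold, whatever their function, were then followed in the mutant cells. The 836 genes higher in WT CD8 SP cells were on balance lower in Thpok-RKF+ than Thpok-RKF- CD4+CD8+ cells, with 38% higher against 51.2% of other genes and a median log2 fold change of -0.20 (camera p = 0.00159, but p = 0.13 with an estimated correlation). Of them 22 rose and 19 fell singly. The set held 16 of 18 cell cycle genes and 18 of 25 cytotoxic lineage genes, and in this comparison camera placed the cell cycle list lower (median -0.72) and the cytotoxic lineage list higher (median 0.22), with neither call kept at an estimated correlation. Without the cell cycle list, a test chosen after seeing the data, 38.3% of the other 820 genes were higher, with a median of -0.19 (camera p = 0.00343, but p = 0.153 with an estimated correlation). The 561 genes higher in WT CD4 SP cells had 53.1% higher and a median of 0.05, and 14 rose and 9 fell (camera p = 0.537 at an inter-gene correlation of 0.01). With no fold threshold on the set this p was 0.000235, and without the libraries numbered 1 it was 0.00101, each towards higher levels in Thpok-RKF+ cells.

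Thpok-RKF- CD4+CD8+ and CD8 SP cells were populations of 1 genotype sorted apart by CD4 and CD8, so Cd4, Cd8a and Cd8b1 are no finding between them. Cd4 was 282 ± 101 CPM in CD4+CD8+ and 26.3 ± 13.2 in CD8 SP cells, a log2 rise of 3.42 ± 0.45 (edgeR, adjusted p = 0.00051), while Cd8b1 fell by 1.12 ± 0.19 and Cd8a had a value of -0.76 ± 0.31 that did not pass, although it passed without the libraries numbered 1 and with these groups alone in the fit (adjusted p = 0.0112 and 0.0342). Zbtb7b, Runx3 and Gata3 had values of 0.18 ± 0.35, 0.06 ± 0.14 and 0.12 ± 0.16 that did not pass. Genes of dividing cells were higher in CD4+CD8+ cells, with the largest fitted rises in Cenpf (4.88 ± 0.59), Mki67 (4.47 ± 0.37), Nusap1 (4.30 ± 0.54) and Kif2c (4.28 ± 0.37). Lrrc32, which encodes a surface protein of regulatory T cells, had no count in CD8 SP cells and was at least 619-fold higher in CD4+CD8+ cells. The largest falls were in Ly6c1 (-2.94 ± 0.33), Tdrd5 (-2.76 ± 0.45), Gprin3 (-1.95 ± 0.44), Dntt (-1.92 ± 0.28), the terminal transferase of immature thymocytes, and Slc28a2b (-1.87 ± 0.19). Gprin3 had adjusted p = 0.131, 0.137 and 0.0521 without Thpok-RKF- CD4+CD8+ replicates 1, 2 and 3 in turn. Gprin3 had adjusted p = 0.0734, 0.0694 and 0.103 without Thpok-RKF- CD8 SP replicates 1, 2 and 3 in turn. Folds moved by over 1.5 times in Cenpf (log2 5.89) and Nusap1 (5.39) without Thpok-RKF- CD8 SP replicate 1.

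Of cell cycle genes 12 rose of 18 (16 rose adjusted over the list alone), with a median log2 fold change of 2.88 (adjusted p = 8.25e-65, and adjusted p = 0.0008 with an estimated correlation). Of regulatory T cell markers 10 rose of 14 (12 rose adjusted over the list alone), including Foxp3 (3.49 ± 0.36), Tnfrsf9 (2.04 ± 0.26) and Tnfrsf4 (2.5 ± 0.34), with adjusted p = 1.06e-31, and adjusted p = 0.0008 with an estimated correlation. Of TCR response genes 7 rose of 18 (12 rose adjusted over the list alone), including Cd5 (1.90 ± 0.13), a negative regulator of TCR signalling, Egr1 (1.59 ± 0.18) and Egr2 (1.68 ± 0.22), with adjusted p = 8.13e-27, and adjusted p = 1.46e-05 with an estimated correlation. Of 12 helper genes, Cd4 and Igfbp4 (1.77 ± 0.24) rose (4 rose adjusted over the list alone; adjusted p = 0.000511, and adjusted p = 0.0115 with an estimated correlation). Because Cd4 was sorted on, the list was tested again without it, a test chosen after seeing the data: 1 of 11 genes rose, with adjusted p = 0.0187, but adjusted p = 0.0841 with an estimated correlation. Cytotoxic genes went both ways, 4 rose and 4 fell of 25 (4 rose and 5 fell adjusted over the list alone; adjusted p = 0.391, median -0.19, mean 0.21, camera direction down), with Dapl1 at 2.60 ± 0.29 and Cst7 at -1.01 ± 0.15. Among 21 effector and memory genes, Anxa2 (2.31), Lgals1 (1.71), Vim (0.89) and Id2 (1.07) rose (7 rose and 3 fell adjusted over the list alone; adjusted p = 0.000335, and adjusted p = 0.0954 with an estimated correlation). That list had a median of -0.09 and a mean of 0.10, with camera direction up. Klf2 (0.94) and Id2 rose among 24 transcription factors, Egr1 and Zfp36 (0.81) among 14 stress genes, and Dntt and Tdrd5 fell among 13 immature thymocyte markers. These lists had adjusted p = 0.0112, 0.0014 and 0.0485, and adjusted p = 0.159, 0.162 and 0.27 with an estimated correlation. Adjusted over the list alone, 4 transcription factors rose and 1 fell, 3 stress genes rose, and 1 immature marker rose and 4 fell. Interferon genes did not pass as a list (adjusted p = 0.8), and 0 of its 26 members were called by edgeR, DESeq2 or limma, with 3 at an unadjusted p below 0.05. Ifi27l2a (0.59) passed without the libraries numbered 1 and Ifit3 (-0.49) with these groups alone in the fit (adjusted p = 0.0108 and 0.0193). Leaving out the libraries numbered 1, 8 of 19 lists passed, 6 of them among the 8 that passed with them. The immature and effector and memory lists then had adjusted p = 0.177 and 0.125, and the cytotoxic and maturation lists passed (adjusted p = 0.0331 and 0.032). For the immature list adjusted p was 0.318 with a term for these libraries and 0.106 with a covariate for reads outside genes, where the maturation list passed (adjusted p = 0.0338). B cell, myeloid, stromal, erythroid and gamma-delta lists had adjusted p = 0.8, 0.748, 0.0684, 0.619 and 0.264. The endothelial gene Cdh5, with 1 count over CD8 SP and 82 over CD4+CD8+ libraries (ratio 79.9, 95% counting interval 13.9 to 3190), was the single member of these lists called (adjusted p = 0.0466), and its call was lost without each of the 6 libraries in turn (adjusted p 0.0863 to 0.209).

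In total 403 genes passed, 284 higher and 119 lower in CD4+CD8+ cells. The count was 231 and 216 without Thpok-RKF- CD8 SP replicates 2 and 3, and 261, 257 and 263 without Thpok-RKF- CD4+CD8+ replicates 1, 2 and 3. DESeq2 called 785, a covariate for reads outside genes gave 644, a required 2-fold change left 266, and leaving out the libraries numbered 1 or adding a term for them gave 516 and 563. Of the 836 genes higher in WT CD8 SP cells, 68.8% were higher in CD4+CD8+ cells against 48.9% of other genes, 133 rose and 24 fell (camera p = 1.19e-16, and p = 0.00185 with an estimated correlation). Cell cycle genes moved with this set, which held 16 of them, while the cytotoxic lineage list, with 18 members in it, did not pass and had camera direction down. Without the cell cycle list, a test chosen after seeing the data, 68.2% of the other 820 genes were higher, 121 rose and 24 fell (camera p = 6.84e-14, and p = 0.00325 with an estimated correlation). Cenpf, Nusap1 and Kif2c are not in that list and were at least 2-fold lower in WT CD4 SP cells, so genes of dividing cells remained in the set. The 561 genes higher in WT CD4 SP cells had 50.3% higher, 36 rose and 7 fell (camera p = 0.132 at an inter-gene correlation of 0.01). At that correlation p was 0.0136 without Thpok-RKF- CD8 SP replicate 1 and 0.0478 without Thpok-RKF- CD4+CD8+ replicate 3, and with no fold threshold the direction turned (p = 0.0248).

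**Figure D3:**
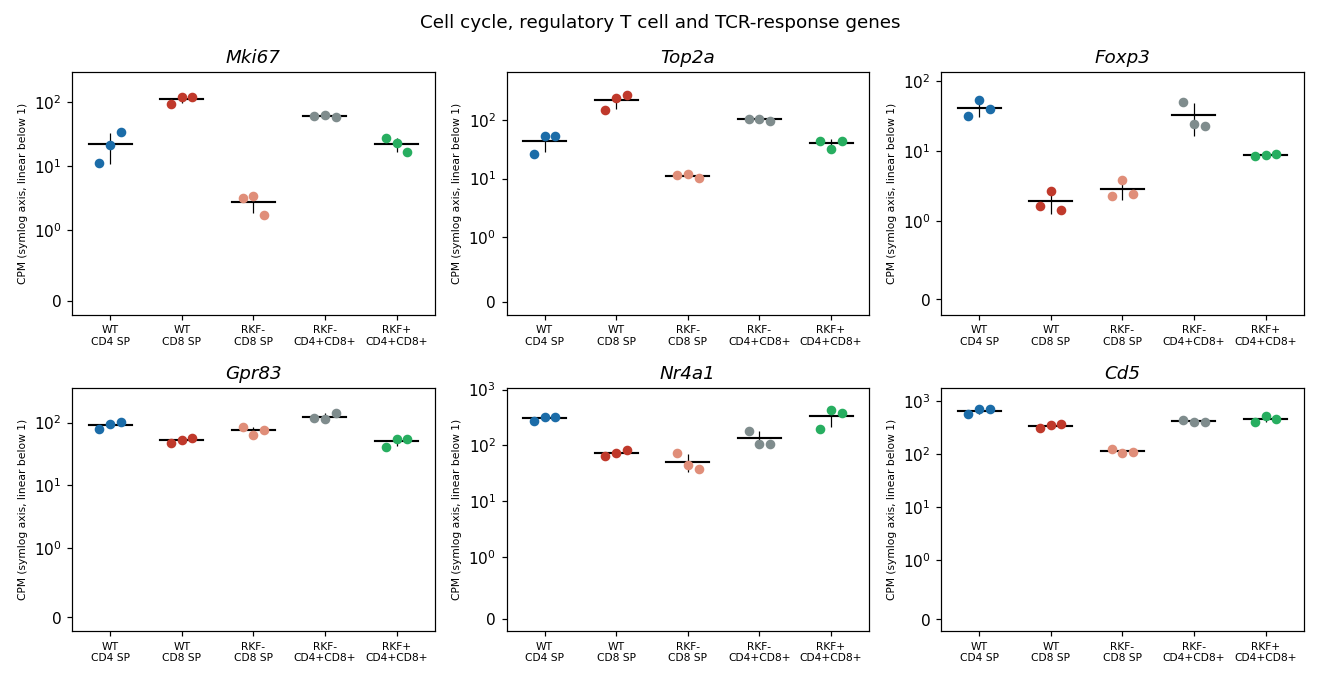
The panels give CPM per group for genes of cell division (Mki67, Top2a), regulatory T cells (Foxp3, Gpr83) and TCR signalling (Nr4a1, Cd5) on a symlog axis that is linear below 1; points are libraries, horizontal lines the mean and vertical lines the SD. Mki67 was 2.72 ± 0.877 CPM in Thpok-RKF- CD8 SP and 60.4 ± 2.82 in Thpok-RKF- CD4+CD8+ cells.

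Thpok-RKF- CD8 SP cells were compared with WT CD8 SP cells of the same surface phenotype but from another host. Zbtb7b was 3.21 ± 0.50 and Cd4 3.82 ± 0.49 log2 units higher in mutant cells, and Gata3 0.86 ± 0.16 (edgeR, adjusted p = 0.000347, 6.13e-05 and 0.00143). Runx3, Cd8a and Cd8b1 had values of 0.38 ± 0.14, 0.02 ± 0.31 and -0.09 ± 0.18 that did not pass, although Runx3 passed by DESeq2, with these groups alone in the fit and with a term for the libraries numbered 1 (adjusted p = 0.0375, 0.0297 and 0.0242). St8sia6 (7.01 ± 0.51), Ly6c1 (6.38 ± 0.40), Khdrbs3 (6.34 ± 0.55) and Tdg-ps2 (7.0 ± 0.28) rose. The guanylate-binding protein gene Gbp2b had 1 count over the WT CD8 SP libraries and 8093 over the mutant libraries, a ratio of 7180 with a 95% counting interval of 1290 to 284000. Tdg-ps2 is named as a pseudogene of Tdg and Gbp2b has the close relative Gbp2, so reads of both pairs are uncertain. Plac8 (-7.55 ± 0.82), Coro2a (-6.02 ± 0.59), the replication gene Mcm10 (-5.53 ± 0.36) and Nusap1 (-5.51 ± 0.57) fell, and Lrrc32 was at least 51.8-fold lower. By limma on normalised values Lrrc32 had adjusted p = 0.149, within a range of 2.43e-07 to 0.149 over all alternatives. Folds moved by over 1.5 times in Nusap1 (log2 -6.58) without Thpok-RKF- CD8 SP replicate 1, Plac8 (-9.01) without Thpok-RKF- CD8 SP replicate 3, Cd4 (4.88) without WT CD8 SP replicate 1 and Khdrbs3 (7.55) without WT CD8 SP replicate 2.

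All 18 cell cycle genes fell in Thpok-RKF- against WT CD8 SP cells (18 fell adjusted over the list alone), with Mki67 at -5.33 ± 0.39, Top2a at -4.30 ± 0.29 and a median of -3.94. Of TCR response genes 1 rose and 11 fell of 18 (1 rose and 11 fell adjusted over the list alone), with Cd5 at -1.61 ± 0.13, Egr3 at -2.85 ± 0.35 and Ikzf2 at -4.33 ± 0.46. Of effector and memory genes 2 rose and 8 fell of 21 (2 rose and 11 fell adjusted over the list alone), with Lgals1 at -4.38 ± 0.19, Anxa2 at -4.57 ± 0.22 and Il18r1 at 3.93 ± 0.34. Of cytotoxic genes 4 rose and 12 fell of 25 (5 rose and 12 fell adjusted over the list alone), with Cst7 at -2.63 ± 0.15, Itgae at -1.99 ± 0.16 and Ly6c2 at -3.25 ± 0.23. Of helper genes 6 rose and 2 fell of 12 (7 rose and 2 fell adjusted over the list alone), with Cd40lg at 4.0 ± 0.30 and Trib2 at 0.80 ± 0.10. These 5 lists passed camera with adjusted p = 1.09e-52, 2.08e-07, 8.71e-09, 0.000128 and 1.91e-05. With an estimated correlation, adjusted p = 0.00477, 0.00477, 0.0124, 0.0175 and 0.00549. Of immature thymocyte markers 4 rose and 2 fell of 13 (5 rose and 2 fell adjusted over the list alone), with Dntt at 3.43 ± 0.30 and Tdrd5 at 5.56 ± 0.52, and the list did not pass (adjusted p = 0.115). In total 3045 genes passed, 1287 higher and 1758 lower in mutant cells, against 3282 without the libraries numbered 1, 3845 with a term for them and 1441 at a required 2-fold change. Without the libraries numbered 1, 8 of 19 lists passed, 5 of them among the 5 that passed with them. The lists gained were NKT and innate-like markers, immature markers and stress genes (adjusted p = 0.01, 0.0426 and 0.0019, against 0.141, 0.115 and 0.242). With all libraries, of NKT markers 1 rose and 4 fell of 13 (3 rose and 4 fell adjusted over the list alone) and of stress genes 4 fell of 14 (1 rose and 4 fell adjusted over the list alone). Of 7 B cell markers, Cd79b (-2.73 ± 0.41) and Ighd (-7.14 ± 0.84) fell (2 fell adjusted over the list alone), while Epcam (1.21 ± 0.27) and Pecam1 (0.42 ± 0.12) rose and Cdh5, with 1 count against 131 in WT libraries (ratio 148, 95% counting interval 26 to 5880), fell among 6 stromal markers (2 rose and 1 fell adjusted over the list alone) and Blk rose among 6 gamma-delta markers (2 rose adjusted over the list alone). Blk and Pecam1 had adjusted p = 0.0734 and 0.0685 without Thpok-RKF- CD8 SP replicate 1. Blk and Pecam1 had adjusted p = 0.122 and 0.0534 without Thpok-RKF- CD8 SP replicate 2. Blk had adjusted p = 0.121 without Thpok-RKF- CD8 SP replicate 3. Blk and Pecam1 had adjusted p = 0.104 and 0.0705 without WT CD8 SP replicate 1. Blk and Pecam1 had adjusted p = 0.131 and 0.0511 without WT CD8 SP replicate 2. Pecam1 and Blk had adjusted p = 0.0926 and 0.0844 without the libraries numbered 1, and Blk had 0.364 by DESeq2. B cell, myeloid, stromal, erythroid and gamma-delta lists had adjusted p = 0.149, 0.537, 0.765, 0.344 and 0.149. The fold moved by over 1.5 times in Ighd (log2 -8.16) without Thpok-RKF- CD8 SP replicate 3.

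The same Thpok-RKF- CD8 SP cells were compared with WT CD4 SP cells from the same kind of host. Zbtb7b fell by 4.70 ± 0.36 and Runx3 rose by 3.21 ± 0.16 on the log2 scale (edgeR, adjusted p = 6.36e-07 and 8.33e-09). The sort fixed Cd4 (-5.08), Cd8a (8.43) and Cd8b1 (6.00). Gata3 had a value of -0.37 ± 0.16 that did not pass, although it passed without WT CD4 SP replicate 1 and without all libraries numbered 1 (adjusted p = 0.0174 and 0.00708). Slc6a19 (12.67 ± 0.51), Cacng4 (8.83 ± 0.51) and Tdg-ps2 (7.73 ± 0.29) rose, Gbp2b was at least 2700-fold higher, Lrrc32 was at least 1150-fold lower, and Itih5 fell by 5.37 ± 0.74. By limma on log2 of CPM plus 1, a scale that holds down folds against levels near 0, Slc6a19, Cacng4 and Tdg-ps2 had values of 9.85, 4.63 and 4.03. Syt10 had 45 counts over WT CD4 SP libraries and none in mutant cells, at least 15-fold lower. Syt10 had adjusted p = 0.0654, 0.0788 and 0.0719 without Thpok-RKF- CD8 SP replicates 1, 2 and 3 in turn. Syt10 had adjusted p = 0.0911 and 0.0534 without WT CD4 SP replicates 1 and 3 in turn. The Syt10 call was also absent without the libraries numbered 1 and by limma on normalised values (adjusted p = 0.179 and 0.21). Of cytotoxic genes 14 rose and 2 fell of 25 (15 rose and 2 fell adjusted over the list alone), including Itgae (4.70 ± 0.18) and the chemokine receptor gene Ccr9 (4.90 ± 0.22). Of regulatory T cell markers 11 fell of 14 (12 fell adjusted over the list alone), of TCR response genes 1 rose and 11 fell of 18 (1 rose and 13 fell adjusted over the list alone), and of helper genes 1 rose and 8 fell of 12 (1 rose and 9 fell adjusted over the list alone). Foxp3 fell by 3.86 ± 0.36, Cd5 fell by 2.54 ± 0.13, Nr4a1 fell by 2.60 ± 0.31 and Icos, a costimulatory receptor gene, fell by 1.04 ± 0.13. The 4 lists had adjusted p = 4.02e-27, 3.94e-17, 5.89e-14 and 2.65e-06, and adjusted p = 6e-05, 0.00485, 0.00019 and 0.00243 with an estimated correlation. Folds moved by over 1.5 times in Itih5 (log2 -6.07) without Thpok-RKF- CD8 SP replicate 1, Cd8a (9.11) without WT CD4 SP replicate 1, Slc6a19 (16.11) without WT CD4 SP replicate 2 and Cacng4 (9.42) without WT CD4 SP replicate 3.

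Of cell cycle genes 14 fell of 18 in the same comparison (14 fell adjusted over the list alone), with Mki67 at -3.01 ± 0.35. Of maturation genes 1 rose and 8 fell of 15 (2 rose and 8 fell adjusted over the list alone), of interferon genes 2 rose and 12 fell of 26 (2 rose and 15 fell adjusted over the list alone), and of immature markers 3 rose and 1 fell of 13 (3 rose and 2 fell adjusted over the list alone). Of effector and memory genes 2 rose and 5 fell of 21 (2 rose and 5 fell adjusted over the list alone), and of stress genes 3 fell of 14 (1 rose and 4 fell adjusted over the list alone). These 6 lists passed with adjusted p = 1.32e-14, 0.000327, 3.24e-05, 0.0241, 0.00967 and 0.0139, but adjusted p = 0.0611, 0.0611, 0.253, 0.221, 0.221 and 0.253 with an estimated correlation. The immature list had adjusted p = 0.0755 with a term for the libraries numbered 1 and 0.267 with a covariate for reads outside genes. Among markers of other cells, Cd79b (2.31 ± 0.43) rose and H2-Ab1 (-3.48 ± 0.70), an MHC class II gene, fell, Col1a1 and Blk had no count in WT CD4 SP cells and were at least 33.4-fold and 119-fold higher, and Cdh5 fell to 1 count from 67 (ratio 66.9, 95% counting interval 11.6 to 2680). Cdh5 had adjusted p = 0.0693 and 0.0648 without Thpok-RKF- CD8 SP replicates 2 and 3 in turn. By limma Col1a1 had adjusted p = 0.051, by DESeq2 Blk had adjusted p = 0.0527, and Cdh5 had adjusted p = 0.0588 with the covariate. Adjusted over the list alone, 1 B cell marker, 1 stromal marker and 2 gamma-delta markers rose and 1 myeloid and 2 stromal markers fell. B cell, myeloid, stromal, erythroid and gamma-delta lists had adjusted p = 0.548, 0.538, 0.976, 0.573 and 0.548. In total 2922 genes passed, 1474 higher and 1448 lower, against 1536 higher and 1995 lower without the libraries numbered 1. The count was 1779 without WT CD4 SP replicate 3, 1613 and 1830 without Thpok-RKF- CD8 SP replicates 2 and 3, 3531 without the libraries numbered 1, 3987 with a term for them and 1374 at a required 2-fold change. The fold moved by over 1.5 times in H2-Ab1 (log2 -2.54) without WT CD4 SP replicate 1.

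Thpok-RKF- CD4+CD8+ cells also differed from WT CD4 SP cells. Zbtb7b and Cd4 fell by 4.53 ± 0.36 and 1.66 ± 0.41 on the log2 scale and Runx3 rose by 3.28 ± 0.16 (edgeR, adjusted p = 1.21e-06, 0.0146 and 6.2e-09). The sort fixed Cd8a (7.68) and Cd8b1 (4.88). Cd4 had adjusted p = 0.0619 and 0.0593 without Thpok-RKF- CD4+CD8+ replicates 2 and 3 in turn. Gata3 had a value of -0.25 ± 0.16 that did not pass, although it passed without the libraries numbered 1 (adjusted p = 0.028). Slc6a19 (11.14 ± 0.50), Cacng4 (9.13 ± 0.51) and Tdg-ps2 (7.77 ± 0.29) rose and Gbp2b was at least 2790-fold higher, while Plac8 (-4.04 ± 0.79), Ly6a (-3.19 ± 0.39), Ctse (-3.07 ± 0.17) and H1f0 (-2.63 ± 0.33) fell. Of cytotoxic genes 14 rose and 3 fell of 25 (16 rose and 3 fell adjusted over the list alone; adjusted p = 2.62e-29, and adjusted p = 3.67e-05 with an estimated correlation), including Ccr9 (4.68 ± 0.22) and Itgae (3.65 ± 0.18). Of interferon genes 1 rose and 15 fell of 26 (2 rose and 17 fell adjusted over the list alone), with Oasl2 at -2.02 ± 0.30 and Gbp3 at 1.39 ± 0.17. Of helper genes 1 rose and 5 fell of 12 (1 rose and 5 fell adjusted over the list alone), with Icos at -0.75 ± 0.13 and Ctsl at 1.09 ± 0.20. Of cell cycle genes 5 rose and 1 fell of 18 (7 rose and 1 fell adjusted over the list alone), with Top2a at 1.21 ± 0.26, and of maturation genes 2 rose and 6 fell of 15 (2 rose and 7 fell adjusted over the list alone), with H2-Q7 at 0.89 ± 0.11. The reads of H2-Q7 and its paralogs are uncertain. These 4 lists had adjusted p = 7.95e-06, 0.0138, 0.0227 and 0.023, and adjusted p = 0.362, 0.0859, 0.481 and 0.362 with an estimated correlation. With Zbtb7b taken out of every list, a test chosen after seeing the data, the helper list had adjusted p = 0.146 and the transcription factor list passed (adjusted p = 0.0121, but 0.289 with an estimated correlation). Leaving out the libraries numbered 1 gave the cell cycle list adjusted p = 0.0613, while regulatory T cell, immature and TCR response lists passed (adjusted p = 2.59e-05, 0.0479 and 0.026). Among markers of other cells, Cd79b rose (2.26 ± 0.43), Col1a1 was at least 77-fold higher, and the haemoglobin gene Hba-a1 fell, with 1 count against 339 in WT CD4 SP libraries (ratio 348, 95% counting interval 62 to 13800). Hba-a1 had adjusted p = 0.0623, 0.0525 and 0.0638 without Thpok-RKF- CD4+CD8+ replicates 1, 2 and 3 in turn. Hba-a1 had adjusted p = 0.0537 without WT CD4 SP replicate 3. It had adjusted p = 0.0541 without the libraries numbered 1. Adjusted over the list alone, 1 B cell and 1 stromal marker rose and 2 erythroid markers fell. B cell, myeloid, stromal, erythroid and gamma-delta lists had adjusted p = 0.446, 0.678, 0.421, 0.459 and 0.964. In total 2908 genes passed, 1514 higher and 1394 lower. The balance turned to 1547 higher and 1784 lower without the libraries numbered 1 and 1983 higher and 2078 lower with a term for them, while a required 2-fold change left 782 higher and 371 lower. The count was 1488 without WT CD4 SP replicate 3, 1823, 1683 and 1676 without Thpok-RKF- CD4+CD8+ replicates 1, 2 and 3, 3331 without the libraries numbered 1, 4061 with a term for them and 1153 at a required 2-fold change. Folds moved by over 1.5 times in Cd8a (log2 8.36) without WT CD4 SP replicate 1, Slc6a19 (14.58) without WT CD4 SP replicate 2 and Cacng4 (9.73) without WT CD4 SP replicate 3.

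Thpok-RKF+ CD4+CD8+ cells were compared with WT CD4 SP cells last. Zbtb7b rose by 3.82 ± 0.33 on the log2 scale and Runx3 by 3.41 ± 0.16 (edgeR, adjusted p = 2.93e-06 and 4.14e-09). The sort fixed Cd8a (8.0) and Cd8b1 (5.02). Cd4 and Gata3 had values of 0.31 ± 0.40 and -0.17 ± 0.16 that did not pass. Slc6a19 (9.52 ± 0.48), Haao (7.68 ± 0.46) and Cacng4 (7.36 ± 0.50) rose and Gbp2b was at least 1920-fold higher. Ckb (-9.77 ± 0.50), Plac8 (-3.10 ± 0.73), the adhesion molecule gene L1cam (-3.08 ± 0.40), Ly6a (-2.88 ± 0.38) and Ctse (-2.81 ± 0.17) fell. Plac8 had adjusted p = 0.0584 without WT CD4 SP replicate 3. With these groups alone in the fit it was 0.122, within a range of 1.03e-05 to 0.122 over all alternatives. Of cytotoxic genes 15 rose and 1 fell of 25 (17 rose and 1 fell adjusted over the list alone; adjusted p = 6.27e-53, and adjusted p = 1.85e-06 with an estimated correlation), including Itgae (4.11 ± 0.18) and Ccr9 (4.17 ± 0.22). Of interferon genes 1 rose and 9 fell of 26 (2 rose and 13 fell adjusted over the list alone), and of regulatory T cell markers 5 fell of 14 (7 fell adjusted over the list alone), including Nt5e (-2.68 ± 0.36) and Foxp3 (-2.24 ± 0.33). Of transcription factors 6 rose and 2 fell of 24 (8 rose and 4 fell adjusted over the list alone), including Zbtb7a (0.83 ± 0.10), and of maturation genes 1 rose and 4 fell of 15 (1 rose and 6 fell adjusted over the list alone), including Cd52 (-1.34 ± 0.17). These 4 lists had adjusted p = 3.72e-05, 4.84e-05, 0.000576 and 0.012, and adjusted p = 0.264, 0.185, 0.137 and 0.185 with an estimated correlation. Leaving out the libraries numbered 1 gave the transcription factor list adjusted p = 0.0586. That list holds Zbtb7b, and with it taken out of every list adjusted p = 0.012, but adjusted p = 0.185 with an estimated correlation. Among markers of other cells, Cd79b (2.76 ± 0.43) and Ighd (4.47 ± 0.80) rose, Col1a1 was at least 26-fold higher, and Maf, counted here as a gamma-delta marker, fell (-4.33 ± 1.24). Maf had adjusted p = 0.106, 0.111 and 0.142 without Thpok-RKF+ CD4+CD8+ replicates 1, 2 and 3 in turn. Maf had adjusted p = 0.12 and 0.0862 without WT CD4 SP replicates 2 and 3 in turn. Without the libraries numbered 1 Ighd had adjusted p = 0.0502, and by limma Col1a1 and Maf had adjusted p = 0.187 and 0.0687. Maf also had adjusted p = 0.0554 with a term for those libraries and 0.078 with a covariate for reads outside genes. Adjusted over the list alone, 2 B cell and 1 stromal markers rose and 2 myeloid and 1 gamma-delta markers fell. B cell, myeloid, stromal, erythroid and gamma-delta lists had adjusted p = 0.119, 0.828, 0.899, 0.097 and 0.782. In total 1202 genes passed, 721 higher and 481 lower, against 1988 by DESeq2, 581 with these groups alone in the fit, 696 at a required 2-fold change, 1009 without the libraries numbered 1 and 1681 with a term for them. Whether this count differs from that of Thpok-RKF- cells against WT CD4 SP cells was not tested. Folds moved by over 1.5 times in Ckb (log2 -13.10) without Thpok-RKF+ CD4+CD8+ replicate 1, Cd8a (8.69) without WT CD4 SP replicate 1, Maf (-3.69) and Slc6a19 (12.97) without WT CD4 SP replicate 2 and Cacng4 (7.96) without WT CD4 SP replicate 3.

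The change from CD8 SP to CD4-expressing cells was then compared between mutant Thpok-RKF- cells and WT cells as a difference of differences. Zbtb7b changed by 7.91 in WT cells and had a value of 0.18 in mutant cells, a difference of -7.74 ± 0.59. Runx3 had -2.84 and 0.06, a difference of 2.90 ± 0.21 (edgeR, adjusted p = 1e-06 and 6.32e-07). Top2a changed by -2.31 in WT and 3.20 in mutant cells. Of 18 cell cycle genes, 18 differed in this direction (18 adjusted over the list alone; camera adjusted p = 7.55e-53, and adjusted p = 0.00208 with an estimated correlation). In total 2360 genes differed, 1401 more positive and 959 more negative in mutant cells. The count was 2337 without the libraries numbered 1, 3160 with a term for them and 1522 at a required 2-fold difference. The mutant CD4-expressing cells also expressed CD8 and the WT hosts differed, so these factors remained confounded.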

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

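Tests of the genotype difference were planned, but only genes and lists that passed are given. The change from CD8 SP to CD4-expressing cells differed between Thpok-RKF- mutant and WT cells for 2360 genes by edgeR, and the values that follow are mutant change minus WT change in log2 units with SE. Negative differences were found for the lineage genes Zbtb7b (-7.74 ± 0.59), Cd4 (-5.48 ± 0.64), Gata3 (-1.12 ± 0.23), Tnfrsf4 (-3.91 ± 0.48) and Satb1 (-0.96 ± 0.11), and positive ones for Runx3 (2.90 ± 0.21), Cd8a (7.66 ± 0.49), Cd8b1 (4.97 ± 0.28), Cst7 (3.28 ± 0.21), Ahr (3.64 ± 0.58), Cxcr6 (2.57 ± 0.53) and Id2 (2.25 ± 0.23). Ly6c1, uncertain because it shares sequence with Ly6c2, had -7.77 ± 0.50, and Pecam1, a member of the stromal list, -0.58 ± 0.17. More positive differences were also found for named genes of cell division, effector and TCR response lists, with Top2a at 5.51 ± 0.38, Anxa2 at 4.06 ± 0.28, Lgals1 at 3.42 ± 0.24 and Cd5 at 0.98 ± 0.18. Col1a1, Hba-a1 and Hbb-bs had fitted differences of 9.66, -12.90 and -13.35, which rest on groups with at most 2 counts and depend on the prior count. The 21 adjusted p-values, under 0.05 by that choice, ran from 6.41e-08 to 0.0343.

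Lists of helper, cytotoxic, TCR response, effector and memory, interferon and cell cycle genes also differed between genotypes by camera, with adjusted p = 2.37e-09, 4.91e-36, 0.00152, 6.75e-06, 1.31e-06 and 7.55e-53. With an estimated correlation, adjusted p = 0.000826, 9.16e-06, 0.0269, 0.0338, 0.208 and 0.00208 in that order, so the interferon list did not pass. Cytotoxic, TCR response, effector and memory and cell cycle genes were on balance more positive in mutant cells, with 16 and 2 of 25, 6 and 1 of 18, 10 and 3 of 21 and 18 and 0 of 18 more positive and more negative members. Helper and interferon genes were on balance more negative, with 1 and 6 of 12 and 2 and 13 of 26. Adjusted over the list alone, these counts were 19 and 2, 11 and 2, 10 and 3, 18 and 0, 1 and 6 and 2 and 16. Of 100 random library splits, the real one included, only that gave as many genes (2360, highest other 542). Splits also remove each genotype's own change, so they cannot exclude chance for the difference. The CD4-expressing mutant cells also carried CD8, and WT CD8 SP cells came from another host, so genotype, surface phenotype and host remain confounded and no biological explanation was tested.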

How the results depend on the processing

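Leaving out the libraries numbered 1, the term for them, the covariate for reads outside genes, lists without Zbtb7b or without the sorted genes Cd4, Cd8a and Cd8b1, and sets without cell cycle genes were chosen after seeing the data; the other alternatives were planned. Over 9316 values of 584 named gene-comparison pairs, 0 called changes turned direction. In report order, 52, 80, 42, 32, 41, 76, 77 and 0 values lost the call. Gains were 11, 93, 52, 31, 25, 15, 37 and 0. The last comparison had only the always named genes. Most losses came with each library left out in turn (245 values) and a required 2-fold change (66). Fold changes moved by over 1.5 times in 84 of 376 called values by limma-trend, all towards 0, since the added 1 holds down folds of low levels, in 40 without the libraries numbered 1, and in 58 of 2292 with 1 library left out. A required 2-fold change, which by construction calls fewer genes, left 1397, 99, 266, 1441, 1374, 1153, 696 and 1522 genes. For Thpok-RKF+ against Thpok-RKF- CD4+CD8+ cells, DESeq2 called 708 genes, no low-count filter 428, limma-trend 287 and only the compared groups 52. Without the libraries numbered 1 the count was 1753, with 154 of the 159 genes kept, and with a term for them 350. For Thpok-RKF- CD4+CD8+ against CD8 SP cells, DESeq2 called 785 and the covariate 644, and for Thpok-RKF+ against WT CD4 SP cells DESeq2 called 1988 and only the compared groups 581. With 1 library left out, counts ran over 1908 to 2623, 50 to 1677, 216 to 311, 2037 to 2700, 1613 to 2669, 1488 to 2626, 832 to 1322 and 1609 to 2231. For the WT helper set in Thpok-RKF+ cells p was 0.000235 with no fold threshold and 0.00101 without the libraries numbered 1, and ran over 0.173 to 0.833 with 1 library left out. For the cytotoxic set there it was 0.13 with an estimated correlation and 0.000184 to 0.00758 with 1 library left out. In Thpok-RKF- cells the helper set turned direction with no fold threshold (p = 0.0248 at an inter-gene correlation of 0.01) and ran over 0.0136 to 0.437 with 1 library left out, while the cytotoxic set ran over 4.48e-19 to 1.65e-15. The number of lists past the threshold was 4, 1, 4, 5, 4, 1 and 1 with an estimated correlation against 10, 5, 8, 5, 10, 5 and 5 at the preset one, and 8 without the libraries numbered 1 for Thpok-RKF- against WT CD8 SP cells. With Zbtb7b left out of the lists it was 3 for Thpok-RKF+ against Thpok-RKF- CD4+CD8+ cells, and 4, 0, 4, 5, 4, 1 and 1 in the 7 comparisons with an estimated correlation. Without the sorted genes it was 10, 5, 8, 5, 10, 5 and 5, and 4, 0, 3, 5, 4, 1 and 1 with an estimated correlation. The cytotoxic list then had adjusted p = 0.000515, 0.000555 and 1.96e-05 in mutant against WT CD4 SP cells. For the other differences, except the required fold change, the cause was not tested. Without cell cycle genes the sets kept their direction and side of the threshold. The replicate number as a replicate block gave 3523, 236, 471, 3610, 3687, 3713, 1533 and 2899 genes and changed no call of a set, moved no count of genes or lists by over 1.5 times, and ended 8 calls of named genes and that of the immature thymocyte list in Thpok-RKF- CD4+CD8+ against CD8 SP cells and Thpok-RKF- CD8 SP against WT CD4 SP cells (adjusted p = 0.359 and 0.0801). It gave 11 calls of named genes and that of the NKT list in Thpok-RKF- against WT CD8 SP cells and Thpok-RKF+ against WT CD4 SP cells (adjusted p = 0.0258 and 0.0261), as did a term for the libraries numbered 1 (0.03 and 0.0255). With the covariate, the interferon list passed in Thpok-RKF- against WT CD8 SP cells (adjusted p = 0.00323), the NuRD list in all 3 mutant groups against WT CD4 SP cells (0.0242, 0.0177 and 0.0216) and the transcription factor list in Thpok-RKF- CD4+CD8+ against WT CD4 SP cells (0.0177). The numbers as a whole did not pair the libraries, since that needs a correlation over 0.1 in every pair: 3 of 21 same-numbered pairs correlated over 0.1 (range -0.05 to 0.22). All of these were pairs of libraries numbered 1, though correlations among libraries numbered 1 ran from -0.014 to 0.22, and 9 of 15 libraries correlated best with their own number. Depth limits genes at or under 3 counts over a group: folds are bounds or ratios with counting intervals, and the fitted values printed or plotted for Col1a1, Hba-a1, Hbb-bs and Syt10 depend on the prior count. In the simulation of Thpok-RKF+ against Thpok-RKF- CD4+CD8+ cells 52.2% of 2-fold changes were recovered.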

Other observations

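The division of called genes by WT direction, the position between WT groups, the tests of the libraries numbered 1, the segment test of Rabl2, Syt10 and Cpne8 and the Gbp2 ratio were chosen after the results were seen. Of the 97 genes higher in Thpok-RKF+ than Thpok-RKF- CD4+CD8+ cells, 26 were higher in WT CD4 SP and 31 in WT CD8 SP cells, where independent lists give 7.48 and 9.99 (2-sided Fisher's exact p = 1.23e-08 and 4.62e-09). The 62 lower genes gave 13 and 23 against 4.78 and 6.38 (exact p = 0.000759 and 1.89e-08). Of the 284 genes higher in Thpok-RKF- CD4+CD8+ than CD8 SP cells, 52 and 151 were so placed against 21.9 and 29.2 (exact p = 6.39e-09 and 2.68e-74), and of the 119 lower genes 24 and 30 against 9.18 and 12.3 (exact p = 1.11e-05 and 2.57e-06). WT and mutant libraries are disjoint but genes are not independent, and excess lay both ways, as genes easy to call anywhere could give. By mixed fry, 17, 8, 15, 18, 18, 15 and 16 of 19 lists changed in the comparisons in report order.

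Each mutant library was also placed between the WT groups by the mean log2 CPM of the helper and cytotoxic genes, with the genes chosen without the WT libraries used as end points. On the helper scale, where WT CD8 SP is 0% and WT CD4 SP 100%, Thpok-RKF- CD8 SP, Thpok-RKF- CD4+CD8+ and Thpok-RKF+ CD4+CD8+ cells stood at 59.5% ± 4.5, 67.5% ± 4.43 and 68.5% ± 5.12 (SD, n = 3). On the cytotoxic scale, where WT CD4 SP is 0% and WT CD8 SP 100%, they stood at 35.8% ± 1.02, 61% ± 1.22 and 50.6% ± 3.93. With the cell cycle list left out the groups stood at 38.9% ± 1.01, 61.6% ± 1.23 and 51.8% ± 4.07, from the cytotoxic lineage list alone at 54.3% ± 2.77, 55.3% ± 4.16 and 76.7% ± 7.87, and from the cell cycle list alone at -96.6% ± 1.44, 33.4% ± 0.651 and -3.62% ± 6.28, so the order of the groups depended on the genes used. In 2-sided exact permutation tests on the helper scale and the full cytotoxic scale, Thpok-RKF+ against Thpok-RKF- CD4+CD8+ cells gave p = 1 and 0.1 in that order, and Thpok-RKF- CD4+CD8+ against CD8 SP cells p = 0.2 and 0.1, where 0.1 is the smallest p that 3 against 3 libraries allow.

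Libraries numbered 1 differed from the others at 1543 genes by edgeR, against 0 and 0 for numbers 2 and 3 (4259, 449 and 1016 at an unadjusted p below 0.05), with Jun (3.12), Fos (1.10), Hspa1a (4.97) and Hspa1b (3.40) among those higher (edgeR, adjusted p = 0.00318, 0.00351, 0.00652 and 0.026). RNA of myeloid cells as the whole cause was argued against, since Lyz2 was highest in the library numbered 1 in 2 of 5 groups, and so was sequencing depth, since the gene total was lowest there in 3 of 5 groups and highest in 1. A stress response during cell isolation stays open: the stress list had camera p = 0.187 with an estimated correlation and p = 0.00397 at the preset one. Cell cycle and interferon genes were lower and immature markers higher with smaller p at the preset correlation, at medians of -0.27, -0.18 and 0.68 against 0.26 for the stress list (p = 8.7e-06, 1.57e-05 and 0.000984, and 0.0878, 0.159 and 0.00982 with an estimated correlation). A shared day of sorting or library preparation may also account for the pattern, but the labels give no dates and no biological explanation was tested.

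Rabl2, Syt10 and Cpne8, neighbours in gene order, were all higher in Thpok-RKF+ than Thpok-RKF- CD4+CD8+ cells, and Cpne8 had 1 count against 3623, a ratio of 3720 with a 95% counting interval of 667 to 147000. A single Thpok-RKF+ library as the cause was argued against, since at least 2 of the 3 genes passed without each in turn (Rabl2 had adjusted p = 0.0556 without replicate 3). A candidate explanation is a chromosomal segment carried with Thpok-RKF: 463 of 10000 random gene sets held a run of 3 within 4 consecutive tested genes. The 155 called genes with a place held 2 runs, the other being Dcst2, Zbtb7b and Gm15417, and 13 random sets held as many. Because the genes were seen before the test was chosen and no coordinates or genotypes were used here, this stays open.

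Gbp2b was at most 0.0266 CPM in every WT library and at least 32.9 CPM in every mutant library. Reads of the related Gbp2 counted as Gbp2b were argued against, since the ratio of Gbp2b to Gbp2 was at most 0.000294 in WT libraries and at least 0.305 in mutant libraries. A segment of another strain in the mutant donors could not be decided: 0 of the neighbours within 10 places on each side changed the same way in all 3 mutant groups, with CD8 SP cells set against WT CD8 SP and both CD4+CD8+ groups against WT CD4 SP, and 100% of positions have at least as many. Set against WT CD4 SP cells alone, the adjoining gene Gbp3 was higher in all 3 mutant groups (log2 fold changes 1.04 ± 0.17, 1.39 ± 0.17 and 1.14 ± 0.17), while it had 0.13 ± 0.17 and did not pass in Thpok-RKF- against WT CD8 SP cells. The labels give 1 strain, C57BL/6, for all samples, and the mutant genotype stays among the open explanations, untested.

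The libraries of a comparison can be divided into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. In each of the 7 comparisons of groups, 1 division, the real one, gave as many changed genes: 2981, 159, 403, 3045, 2922, 2908 and 1202, with highest other counts of 1, 1, 1, 0, 0, 1 and 1 in the order of the report. For the cytotoxic set 1 and 1 division had a camera p (inter-gene correlation 0.01) as small in Thpok-RKF+ against Thpok-RKF- CD4+CD8+ cells and in Thpok-RKF- CD4+CD8+ against CD8 SP cells (real p = 0.00159 and 1.19e-16, smallest other 0.0083 and 2.14e-05). For the helper set 9 and 4 divisions had one as small at that correlation (real p = 0.537 and 0.132, smallest other 0.00121 and 0.00417). As many gene lists passed in 1, 1, 1, 5, 2, 1 and 2 divisions, with real counts of 10, 5, 8, 5, 10, 5 and 5 and highest other counts of 8, 2, 5, 7, 11, 3 and 6.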
